A study of Mus musculus with 6 samples.

How the data were processed

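RNA was extracted with TRIzol and sent to a commercial company for library preparation and sequencing, per the labels' protocols. The deposited table holds whole-number counts per gene for 6 libraries and 56748 genes, not normalized, with 1 column per library. Per the submitters' processing notes, Salmon and limma were used and the builds GRCm38 and mm10 are named, without saying which step each belongs to. Whether the deposited counts are read counts or rounded Salmon estimates, how strand was used, and which filters were applied are not given in the sources used here. The table's gene coordinates differ from GRCm38: of 52073 gene identifiers shared with the GENCODE M21 annotation of that build, 1485 (2.85%) had the same start. Coordinates are therefore printed as the deposited table gives them, with no build named. The deposited table also gives a gene length, which entered no test. Gene names and biotypes are those of the table, and 632 of 633 symbols in the gene lists were found in it, the missing one being Ahsp.

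Groups were taken from the sample titles, 3 libraries labelled Rbm5 knockout and 3 labelled wild type, with no batch or pairing named. The title numbers are not shared between groups. No pair of libraries was alike within sampling noise, with a lowest chi-square per degree of freedom of 39.3. Totals were 26359299 to 31807588 counts, and 97.4% to 97.9% of counts fell on protein-coding genes. Intervals from counts cover counting error only.

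The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 15963. Counts were scaled by TMM and tested with edgeR's robust quasi-likelihood fit (R 4.3.3, edgeR 4.0.16), knockout against wild type without covariates. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The SE of a log2 fold change was taken from the fold change and its F statistic, and 95% intervals from the t distribution with the fit's degrees of freedom. Means and SDs are of TMM-scaled CPM. Where a group had 0 counts, the fold was computed against 3 counts over the group and given as a lower limit, and with 1 to 3 counts as a ratio with an exact counting interval.

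The lists, 30 in number, covered the MLL self-renewal program, MYC targets, other programs, markers of marrow cell types, and handling or sex genes. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at the preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The tests were repeated with the correlation estimated from the data and with fry. Members were counted as higher or lower by the edgeR test over all genes, and again adjusted over the list alone.

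Named genes were Rbm5, Rbm6, Rbm10, Myc, Hoxa9 and Meis1, whatever their values, and the 10 largest rises and 10 largest falls among protein-coding genes. The latter had to pass the threshold with a mean of at least 1 CPM over the 6 libraries and groups that did not overlap, and predicted genes were not named. Of each list, up to 4 called members with the smallest p were named, or, with none called, the 2 members with the smallest p. Single members could be given as values where the whole list is described, and a few genes that the rule allows are not reported here. The other genes of the Hoxa cluster were singled out after their values were seen.

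The procedure was tested on simulated data. Counts of 15963 genes were drawn from the means and library sizes of the knockout and wild-type libraries, with 200 genes changed in each of 10 draws. Changed genes were drawn from the better-expressed ones only, so the shares recovered hold for those. It recovered 9.25% of genes changed 1.5-fold, 59.7% changed 2-fold and 89.2% changed 4-fold, and 9.4% of its calls were false. A simulated set of 30 genes changed 1.5-fold was called by camera with either correlation and by fry. Of 29 unchanged sets, camera called 0. Simulated genes varied independently, so this did not test camera's preset correlation on lists whose genes vary together. In the data, estimated correlations ranged from -0.177 (sex-linked genes) to 0.79 (immediate early and handling stress genes), with 0.245 for MYC targets.

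Alternatives were the RLE and upper-quartile factors, total counts alone, no filter, at least 1 CPM in 3 libraries, and the fit without robust shrinkage. Further alternatives left out each library in turn, or left out haemoglobin, immunoglobulin and mitochondrial genes. DESeq2 1.42.0, limma-voom with and without quality weights, and a test against a fold of 1.5 (glmTreat) were also run. After the data were seen, fits were added that left out wild-type libraries 27 and 29 (leaving 1 wild-type library), genes on chromosomes X and Y, and genes on chromosome 6. Medians by chromosome, also taken after the data were seen, used genes with a mean log2 CPM above 4. All 10 divisions of the 6 libraries into 3 and 3 were tested.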

Results

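Bulk RNA sequencing was used to compare mouse leukemia cells labelled as lacking Rbm5 with cells labelled wild type. The leukemia was driven by MLL-AF9, a fusion of the histone methyltransferase MLL with AF9 that turns myeloid progenitors into acute myeloid leukemia. RBM5 is an RNA-binding protein that takes part in pre-mRNA splicing. The series asked how RBM5 acts on the self-renewal program of MLL leukemia, and its title also names the transcription factor MYC. The 6 libraries comprised 3 labelled knockout (numbers 31, 32 and 40) and 3 labelled wild type (numbers 25, 27 and 29). Their labels call them independent replicates, but describe the source both as whole bone marrow and as cultured cells. Total counts were 31807588, 27140474 and 31528961 in wild-type libraries 25, 27 and 29, and 27638075, 26359299 and 26983461 in knockout libraries 31, 32 and 40. Across genes, which are not independent replicates, Pearson's r between the log2 profiles of libraries was 0.973 to 0.977 within a group and 0.926 to 0.962 between groups, and 0 libraries lay nearest to a library of the other group. The first principal component carried 55.3% of the variance and separated the groups.

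Rbm5 itself was not lower in the libraries labelled knockout. The gene (ENSMUSG00000032580, chromosome 9, 107617570 to 107648195, minus strand, in the deposited table's coordinates, for which no build is named there) was at 227.5, 214.1 and 173.6 CPM (counts relative to TMM-scaled library size) in wild-type libraries 25, 27 and 29. It was at 269.0, 266.7 and 245.3 CPM in knockout libraries 31, 32 and 40. The means were 205.0 ± 28.1 CPM in wild type and 260.4 ± 13.1 CPM in knockout (SD, n = 3 each). The log2 fold change, knockout minus wild type, was 0.34 (95% confidence interval 0.08 to 0.61), and the adjusted p of edgeR's quasi-likelihood test was 0.107. The table holds 1 count per gene, so the loss of single exons could not be read from it, and 1 annotated gene overlaps Rbm5 on the other strand. Its paralogs Rbm6 and Rbm10 had log2 fold changes of 0.03 and 0.16 (edgeR adjusted p = 0.846 and 0.345). Rbm6 turned to -0.01 with upper-quartile factors and to -0.09 with total-count scaling. Because the targeted gene did not fall, the words knockout and wild type stand below for what the libraries were labelled, and each direction rests on those labels.

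The groups also differed fully in the transcripts that mark sex. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in each wild-type library. In knockout libraries 31, 32 and 40, Ddx3y had 2645, 2674 and 3311 counts. Against a floor of 3 counts over the wild-type group, these genes were at least 3500-, 3030-, 1400- and 685-fold higher in knockout. Xist, the noncoding RNA that silences the inactive X chromosome in females, averaged 1420 ± 185 CPM in wild type. It stood at 0.918%, 13.5% and 2.29% of that mean in knockout libraries 31, 32 and 40 (edgeR adjusted p = 0.0701). Sex and the knockout label therefore could not be separated in any comparison of these libraries. Of the 1368 genes called below, 38 lay on X, 8 on Y and 1322 on neither.

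**Figure D1:**
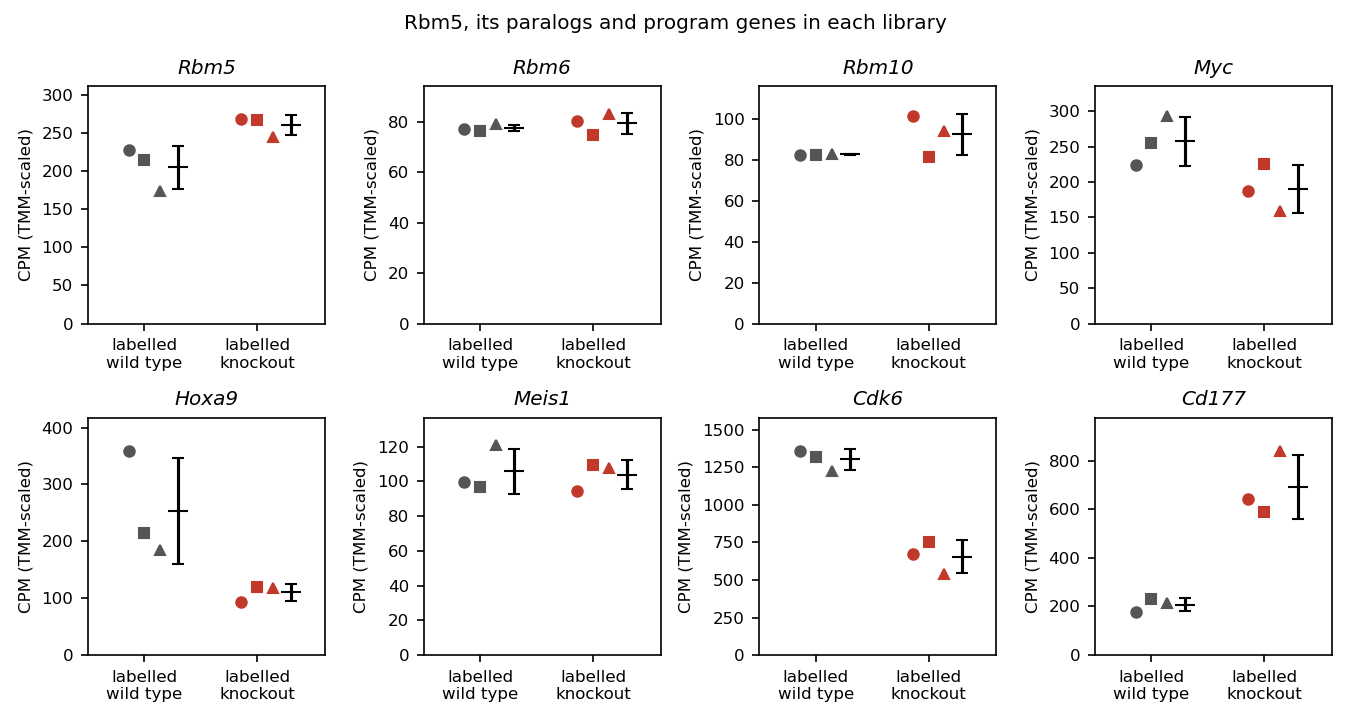
TMM-scaled CPM (y axis, from 0) of 8 genes in each library labelled wild type (grey; circle 25, square 27, triangle 29) and knockout (red; circle 31, square 32, triangle 40), with the mean and SD of each group of 3 in black. Rbm5 averaged 205.0 CPM in wild type and 260.4 CPM in knockout, while Cdk6 fell from 1303 to 655.9 CPM and Cd177 rose from 208.0 to 691.8 CPM.

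Of 15963 genes tested with edgeR, 1368 passed an adjusted p of 0.05, with 870 higher and 498 lower in the libraries labelled knockout. At least 2-fold changes made up 416 of the higher and 260 of the lower genes, and 801 and 452 were protein coding. Groups did not overlap for 5374 of the tested genes (33.7%, where chance gives 10%). With total counts as the only scaling, which moved the median log2 fold change of all genes by -0.12, 597 were higher and 682 lower (46.7% higher, against 63.6% with TMM). Without knockout library 40, 245 were higher and 102 lower. Without knockout library 31 the numbers were 357 and 137, and without wild-type library 25, 27 or 29 they were 409 and 239, 446 and 213, and 468 and 223. Genes on chromosome 6 made up 15.5% of the lower genes (77 of 498) and 5.36% of those tested. Over the 390 of them with a mean log2 CPM above 4, the median was 0.36 higher on the log2 scale in wild-type libraries 27 and 29 than in the other 4 libraries. Leaving these 2 libraries out leaves 1 wild-type library, assumed to vary like the knockout libraries from which alone the spread is then estimated. That fit called 305 genes higher and 148 lower, of which 319 were shared with the full comparison.

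**Figure D2:**
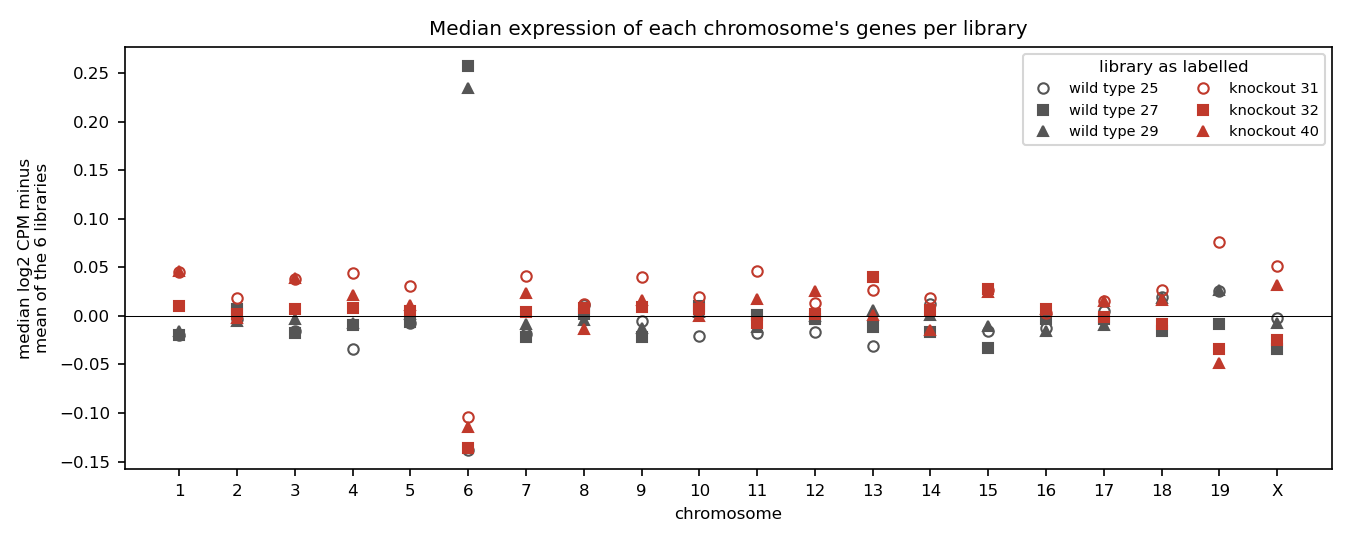
Median, over the genes of each chromosome (x axis) with a mean log2 CPM above 4, of log2 CPM minus the mean of the 6 libraries (y axis), for each library labelled wild type (grey) or knockout (red). Wild-type libraries 27 and 29 stand above the rest on chromosome 6, whose 390 such genes had a median 0.36 higher there than in the other 4 libraries, while no other chromosome moved by more than 0.0419 in that contrast.

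Beyond the Y-linked genes, the 10 protein-coding genes with the largest rises included Mecom, Sva, Zfp987, Tmem45a2, Dock1 and Col6a6. Mecom, a zinc finger transcription factor of hematopoietic stem cells, had 1 count over the wild-type group and 683 over the knockout group (ratio 831, 95% counting interval 149 to 32900). Its CPM in knockout libraries 31, 32 and 40 was 16.5, 0.382 and 9.40, and its edgeR adjusted p of 0.0375 rose to 0.16 without wild-type library 29. Sva and Zfp987 had 0 counts in wild type and were at least 78.7- and 67.3-fold higher, and Tmem45a2 had 2 counts (ratio 114, interval 31.2 to 951). Dock1, an activator of the GTPase RAC, rose from 0.188 ± 0.0764 to 16.0 ± 4.70 CPM (log2 fold change 6.36 ± 0.41 SE, edgeR adjusted p = 5.31e-04). Col6a6, a collagen VI chain, rose by 5.52 ± 0.42 on that scale (adjusted p = 0.00145). Such intervals and floors cover counting error only.

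Aldh1a7, an aldehyde dehydrogenase, was lost to 0 counts in knockout, at least 75.1-fold lower than its 2.90 ± 1.45 CPM in wild type. Ckmt1, a mitochondrial creatine kinase, had 301 counts in wild type and 1 in knockout (ratio 247, interval 44.1 to 9800), and the neighboring Strc, which overlaps it on the other strand, fell by 6.17 on the log2 scale. Sncaip, Susd5, As3mt, Myh15, Col6a3, Vldlr and Dmrta2 fell too, with log2 fold changes from -7.19 (Sncaip) to -5.18 (Dmrta2). Col6a3, another collagen VI chain, went from 12.8 ± 2.69 to 0.249 ± 0.111 CPM (edgeR adjusted p = 6.35e-04). How the counts used strand is not given in the sources used here, so reads where genes overlap are uncertain. Strc and Ckmt1 overlap only from 121194209 to 121194218 in the table's coordinates, a small part of either gene. Of 65 named genes past the threshold, each kept its sign and 21 stayed past it whichever single library was left out. In this group Tmem45a2, Susd5, Strc, Vldlr and Dmrta2 did not, with highest adjusted p of 0.0662 (without wild-type library 29) for Tmem45a2 and, for the others, 0.0698 (knockout 40), 0.0653, 0.0601 and 0.0625 (knockout 31).

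In the self-renewal program of MLL leukemia, Cdk6 and several Hoxa genes were lower in the libraries labelled knockout, while Meis1 did not pass the test. Of 25 tested members, 6 fell (Hoxa3, Hoxa6, Hoxa7, Hoxa9, Cdk6 and Runx2), 1 rose (Mecom) and 18 did not pass the test. Adjusted over the list alone, 9 fell and 1 rose. With 1 library left out, the number that fell over all genes ranged from 1 (without knockout library 31 or 32) to 3 (without wild-type library 29). Hoxa9, the homeobox gene on which MLL leukemias depend, went from 253.0 ± 93.5 to 110.3 ± 15.2 CPM (log2 fold change -1.20 ± 0.26 SE, edgeR adjusted p = 0.0375). Cdk6, a cell cycle kinase, went from 1303 ± 68.8 to 655.9 ± 108 CPM (log2 fold change -0.99 ± 0.13 SE, adjusted p = 0.00802), and Runx2 fell by 0.50 on the log2 scale. Meis1, the usual partner of HOXA9, had a log2 fold change of -0.03 (95% interval -0.29 to 0.24, adjusted p = 0.909). Other members went either way without passing the test, among them Flt3 at -0.88, Eya1 at 2.74 and Mef2c at 0.39. The list median was -0.64, and camera gave an adjusted p of 0.00712, which was 0.698 with an estimated correlation. Without knockout library 32 it was 0.0699, and without chromosome 6 genes 0.523. Cdk6 stayed past the threshold whichever library was left out, whereas Hoxa9 reached 0.119 without knockout library 40 and Runx2 0.138.

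All 10 tested genes of the Hoxa cluster (chromosome 6, 52132570 to 52222790, in the table's coordinates) had negative log2 fold changes, from -4.26 (Hoxa11) to -1.09 (Hoxa7), with a median of -1.71. Of these, Hoxa3, Hoxa4, Hoxa6, Hoxa7 and Hoxa9 passed the edgeR test. Hoxa4 went from 7.54 ± 2.39 to 1.58 ± 0.626 CPM (adjusted p = 0.0174), while Hoxa5, at 125.7 ± 64.4 and 34.1 ± 11.3 CPM, did not pass (adjusted p = 0.0527). Wild-type libraries 27 and 29, in which chromosome 6 genes stood higher, had 215.1 and 184.4 CPM of Hoxa9, below the 359.6 CPM of library 25. Against wild-type library 25 alone the cluster's median was -2.40.

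MYC target genes passed as a group, with lower values in the libraries labelled knockout, only at the preset correlation of camera, and no member's log2 fold change lay outside -0.77 to 0.81. Of 52 tested members, 47 had negative values, 9 fell, 0 rose and 43 did not pass the test; adjusted over the list alone, 26 fell. The members that fell included Nop2 (log2 fold change -0.66 ± 0.11 SE, edgeR adjusted p = 0.0147), Nop16 (-0.56), Ppan (-0.48) and Rcl1 (-0.73). Nop2, which lies on chromosome 6, went from 153.8 ± 12 to 97.0 ± 10.2 CPM. Myc itself was at 257.2 ± 34.8 CPM in wild type and 190.5 ± 33.8 CPM in knockout (log2 fold change -0.43, 95% interval -0.78 to -0.08, adjusted p = 0.115). The list median was -0.35, and camera gave an adjusted p of 1.38e-07, which was 0.698 with an estimated correlation and 0.0741 by fry. Nop2 stayed past the threshold whichever library was left out, but Nop16, Ppan and Rcl1 reached 0.0718 and 0.0842 (without knockout 40) and 0.0723 (without wild-type 27), and the count of fallen members ranged from 1 (without wild-type 27) to 8 (without knockout 32), and was 1 against wild-type library 25 alone, an arm of 1 library.

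Ribosomal protein genes did not pass the test, and few genes of the respiratory chain did. Of 78 cytosolic ribosomal protein genes, 0 passed the edgeR test over all genes or adjusted over the list alone, although 4 had an unadjusted p under 0.05 (median -0.10, and -0.138 to -0.0596 without wild-type library 27 or 29, camera adjusted p = 0.0737, and 0.018 to 0.414 without knockout library 40 or 31). Rpl12 and Rps2 had log2 fold changes of -0.38 and -0.31. Among 48 nuclear oxidative phosphorylation genes, Ndufv1 and Ndufa4 of complex I fell by 0.38 and 0.61 on the log2 scale and 46 did not pass the test, with 0 called when adjusted over the list alone. The list median was -0.12 (-0.0782 without wild-type library 29) and its camera adjusted p was 0.0138, or 0.698 with an estimated correlation, 0.124 without wild-type library 29, 0.0537 without knockout library 32 and 0.245 against wild-type library 25 alone. Neither Ndufv1 nor Ndufa4 (on chromosome 6) stayed past the threshold in any fit that left out 1 library. Of 13 mitochondrially encoded mRNAs, mt-Nd2 fell by 0.51 and 12 did not pass; adjusted over the list alone, 6 fell. Their median was -0.47 and the camera adjusted p 0.00712, or 0.698 with an estimated correlation, 0.0656 without knockout library 31, 0.0582 without wild-type library 29 and 0.0873 against wild-type library 25 alone, an arm of 1 library.

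Genes of mature neutrophils were higher in the libraries labelled knockout. Of 20 tested members, 15 rose and 5 did not pass the edgeR test; adjusted over the list alone, all 20 rose. Cd177, a neutrophil surface glycoprotein, went from 208.0 ± 27.2 to 691.8 ± 132 CPM (log2 fold change 1.73 ± 0.16 SE, adjusted p = 0.00274). Fpr1, the formyl peptide receptor, rose by 4.59 ± 0.50 (adjusted p = 0.00608), the gelatinase gene Mmp9 by 2.76 ± 0.31, and Stfa2l1 by 4.43 ± 0.45, a stefin whose near-identical neighbors make its count uncertain. The secondary granule gene Ltf rose by 4.37, and S100a8 and S100a9 by 3.12 and 3.17. Camp, Ngp, Chil3, Cxcr2 and Mmp8 had values of 1.56 to 3.37 without passing over all genes. Cd177, Fpr1, Mmp9 and Stfa2l1 stayed past the threshold whichever library was left out. The list median was 3.09, and camera gave an adjusted p of 1.5e-28, which was 0.263 with an estimated correlation. The number that rose was 8 without knockout library 31, knockout library 40 or wild-type library 27, and 5 against wild-type library 25 alone, an arm of 1 library.

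**Figure D3:**
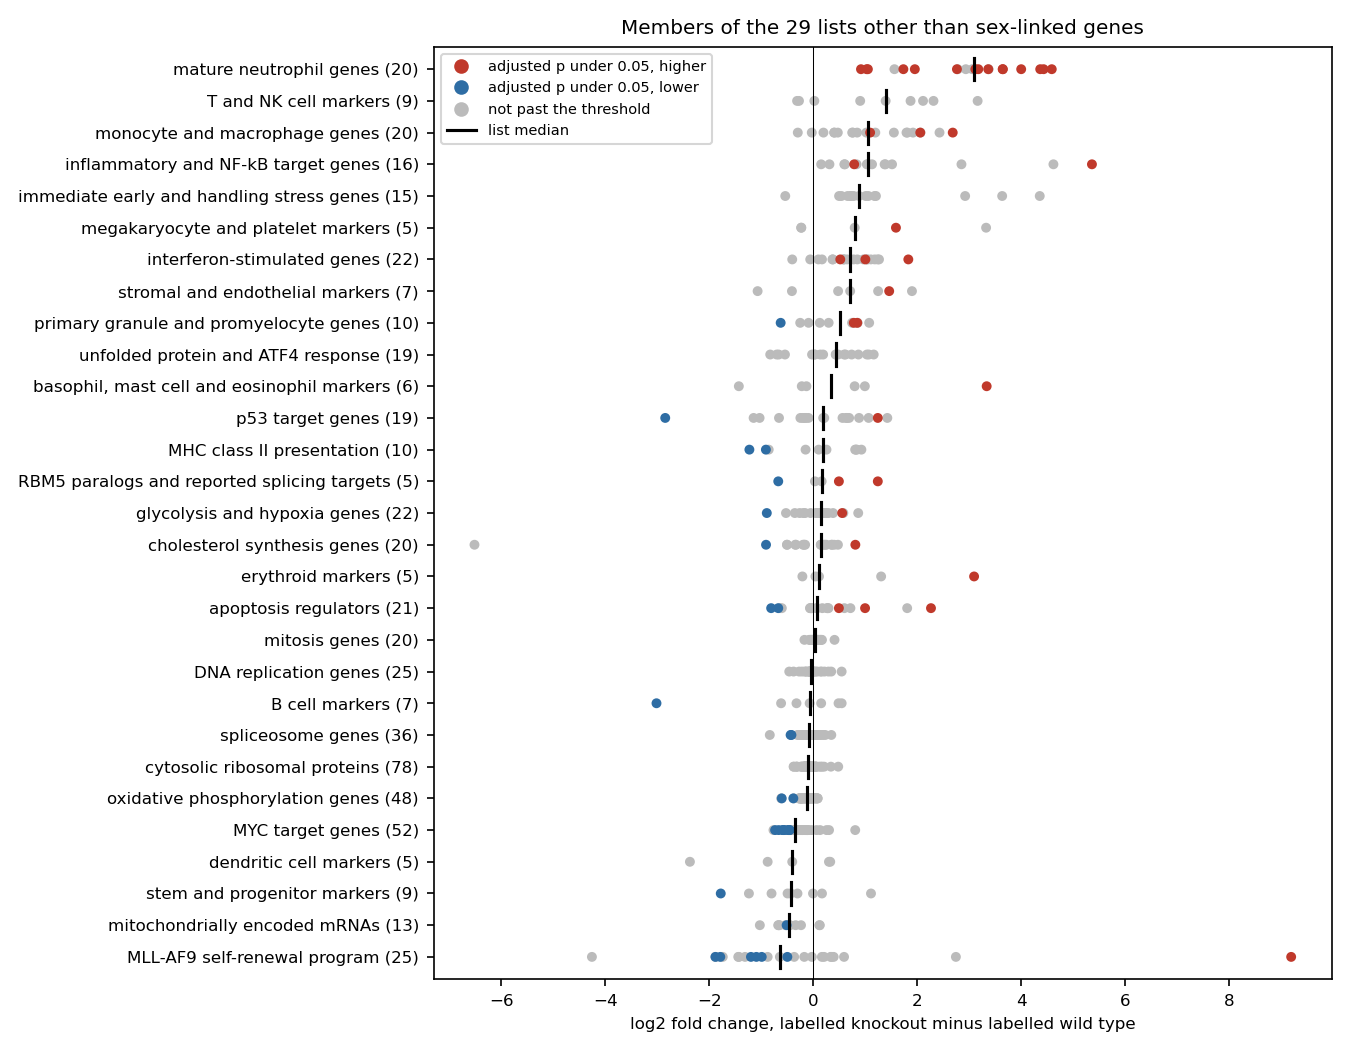
Log2 fold changes (x axis, knockout minus wild type as labelled) of the tested members of 29 gene lists (y axis, number tested in parentheses), with the members past the edgeR threshold in red (higher) or blue (lower), the others in grey, and each list's median as a black bar. Mature neutrophil genes stand highest, with a median of 3.09, and the self-renewal program lowest, with a median of -0.64; the fitted value of Mecom at the far right depends on the prior count.

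Genes of earlier granules were mixed. Of 10 primary granule and promyelocyte genes, Cebpe, a transcription factor of granulocyte maturation, rose by 0.85 and the protease gene Prtn3 by 0.78 on the log2 scale, while the protease gene Ctsg fell by 0.63 and 7 did not pass the edgeR test. Adjusted over the list alone, 4 rose and 1 fell (median 0.52, and 0.251 to 0.789 without knockout library 31 or wild-type library 29, camera adjusted p = 0.129, and 0.00697 to 0.468 without wild-type library 29 or 27). Of 20 monocyte and macrophage genes, 3 rose over all genes and over the list alone, and 17 did not pass. The lysozyme gene Lyz2 went from 653.9 ± 289 to 2725 ± 939 CPM (log2 fold change 2.06 ± 0.39 SE, adjusted p = 0.0308), Csf1r, the receptor of macrophage colony-stimulating factor, rose by 1.09, and Ms4a7 by 2.68 from 0.115 CPM. The list median was 1.06 (0.643 without knockout library 40) and its camera adjusted p 2.18e-04, or 0.698 with an estimated correlation. Of these genes, 0 rose without knockout library 31 or 40. Lyz2 reached 0.0898 without wild-type library 29, and Csf1r 0.0786 and Ms4a7 0.183 without knockout library 40. Highest values for Cebpe, Prtn3 and Ctsg were 0.0576 (without wild-type 27), 0.139 (wild-type 25) and 0.115 (knockout 40).

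Interferon-stimulated genes had a median of 0.71 (0.20 without knockout library 31), with 3 of 22 past the edgeR test over all genes and over the list alone. These were Cmpk2 (log2 fold change 1.00 ± 0.22 SE, adjusted p = 0.0354), Stat2 (0.52) and Rsad2 (1.83), an antiviral enzyme, and 0 passed without wild-type library 25 or 27 or knockout library 31 or 40. The camera adjusted p was 0.00764, or 0.698 with an estimated correlation, 0.258 without knockout library 31, 0.0604 without wild-type library 27 and 0.422 against wild-type library 25 alone, an arm of 1 library. Inflammatory and NF-kB target genes were above 0 in 16 of 16 members. Icam1, an adhesion receptor, rose by 0.79 and the cytokine gene Il1b from 0.940 ± 0.393 to 39.1 ± 46.6 CPM (log2 fold change 5.36 ± 1.16 SE, adjusted p = 0.0484), while 14 did not pass; adjusted over the list alone, 8 rose. The list median was 1.06 (0.56 without knockout library 40) and the camera adjusted p 9.05e-05, or 0.698 with an estimated correlation. The number that rose was 0 without wild-type library 25, wild-type library 27 or knockout library 31, and 4 without knockout library 32. Immediate early and handling stress genes had a median of 0.88 (0.421 without knockout library 40 and 1.46 without wild-type library 29), but 0 of 15 passed by edgeR over all genes or over the list alone, and 4 had an unadjusted p under 0.05. Of the 15, 2 rose over all genes without knockout library 32. The list's camera adjusted p was 0.00712, or 0.698 with an estimated correlation, and 0.0619, 0.0617 and 0.0604 without wild-type library 25, wild-type library 27 or knockout library 40. It was 6.67e-06 without wild-type library 29 and 1.43e-04 without knockout library 32. Hspa1a and Hspa1b, near-identical heat shock genes whose counts are uncertain, had 641.1 and 1149 CPM in knockout library 31, 68.0 and 113.9 in library 32, and 865.8 and 1126 in library 40. In wild-type libraries 25, 27 and 29, Hspa1a had 19.03, 10.35 and 47.41 CPM. Hspa1b had 38.26, 31.77 and 122.3 CPM there, so its groups overlapped. Their log2 fold changes were 4.36 and 3.63 (edgeR adjusted p = 0.0695 and 0.0905). Without 1 library, the highest adjusted p was 0.116, 0.126 and 0.149 for Cmpk2, Stat2 and Rsad2 (knockout 40), 0.0764 for Icam1 (wild-type 27) and 0.169 for Il1b (wild-type 25).

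Genes of cell death went both ways. Of 21 apoptosis regulators, Cflar, Bcl2a1a and Mcl1, which restrain death, rose by 0.49, 2.27 and 1.00 on the log2 scale, Bid and Casp2, which promote it, fell by 0.81 and 0.67, and 16 did not pass the edgeR test. Adjusted over the list alone, 7 rose and 2 fell (median 0.07, or -0.06 with total-count scaling and 0.153 without knockout library 32, camera adjusted p = 0.358). Bid and Casp2 both lie on chromosome 6, and Bcl2a1a belongs to a family of near-identical copies, which leaves its count uncertain. The transcripts of Fas, Cflar and Casp2 have been reported as splicing targets of RBM5. With Rbm6 and Rbm10 they formed a list of 5, in which Fas (log2 fold change 1.24 ± 0.27 SE, adjusted p = 0.0307) and Cflar rose and Casp2 fell, over all genes and over the list alone (median 0.16, and 0.0883 to 0.245 without knockout library 31 or 32, camera adjusted p = 0.50). These are gene totals, and isoforms were not analysed here. Of 19 p53 target genes, Fas rose and Perp fell by 2.85, with the same count over the list alone (median 0.19, and -0.0287 to 0.268 without wild-type library 27 or knockout library 31, camera adjusted p = 0.845). The log2 fold change of Perp was -1.79 without wild-type library 25 and -3.24 without wild-type library 27. Among 36 spliceosome genes, Prpf31 and Snrnp70 fell by 0.42 and 0.44, and 0 were called over the list alone (median -0.08, and -0.128 to -0.0201 without wild-type library 25 or 29, camera adjusted p = 0.211). Without knockout library 40 the adjusted p was 0.0703 for Bid, 0.0786 for Casp2, 0.125 for Cflar, 0.14 for Bcl2a1a, 0.108 for Fas, 0.146 for Perp, 0.108 for Prpf31 and 0.121 for Snrnp70.

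Proliferation genes did not pass the test over all genes. By edgeR, 0 of 20 mitosis genes and 0 of 25 DNA replication genes passed over all genes or over the list alone, with 1 and 3 at an unadjusted p under 0.05 (medians 0.03 and -0.04, camera adjusted p = 0.715 for both). The mitosis median turned to -0.09 with total-count scaling. Without knockout library 31 the 2 medians were -0.0534 and -0.204, without knockout library 32 the mitosis median was 0.148, and without knockout library 40 the DNA replication median was 0.103. Mki67 and Ccne2, whose groups did not overlap, had log2 fold changes of 0.41 and 0.55, and Mki67 passed without knockout library 32 (edgeR adjusted p = 0.0406). Ccnb1 and Mcm2 were at -0.17 and -0.46, with overlapping groups. Mcm2, on chromosome 6, had 276.4 CPM in wild-type library 25 and 279.8 CPM in knockout library 31. Of 22 glycolysis and hypoxia genes, Ndrg1 rose by 0.56 and Egln3 fell by 0.89, with 2 higher and 1 lower over the list alone (median 0.15, and 0.0782 to 0.214 without wild-type library 25 or 29, camera adjusted p = 0.523). Of 19 genes of the unfolded protein and ATF4 response, 0 passed by edgeR over all genes and 7 had an unadjusted p under 0.05; over the list alone 2 rose and 2 fell (median 0.43, and 0.0671 without wild-type library 27 or 0.173 without knockout library 40, camera adjusted p = 0.358, and 0.0418 to 0.779 without wild-type library 29 or 27). Atf4 and Asns, an asparagine synthetase on chromosome 6, had values of 0.74 and -0.66. Of 20 cholesterol synthesis genes, 1 rose (Mvd, by 0.81), 1 fell and 18 did not pass, and over the list alone 1 rose and 3 fell. That list's median was 0.15 (-0.117 to 0.329 without knockout library 40 or 32), but its mean of -0.30 and its test pointed down (camera adjusted p = 0.646). The highest adjusted p without 1 library was 0.112 for Ndrg1 and Egln3 (knockout 40), and 0.0825 for Mvd (wild-type 25).

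Markers of other marrow cells were mostly low, and most did not pass the edgeR test. Of 9 stem and progenitor markers, Angpt1 fell by 1.78 on the log2 scale (55.5 ± 24.2 to 16.2 ± 5.56 CPM), the only call over all genes and over the list alone, while Kit and Cd34 had values of -0.49 and -0.43 (median -0.43, -0.267 without wild-type library 25 and -0.244 without knockout library 40, camera adjusted p = 0.169, 0.0259 to 0.545 without wild-type library 27 or 25, and 0.0132 against wild-type library 25 alone, an arm of 1 library). Of 10 class II antigen presentation genes, H2-Ab1 and H2-Ob fell by 0.91 and 1.23, over all genes and over the list alone; the median of 0.18 (-0.0201 without knockout library 31) and mean of 0.06 lay above 0 while the test pointed down (camera adjusted p = 0.373). T and NK cell markers had a median of 1.39 (0.625 without knockout library 31, 2.14 without knockout library 32) with 0 of 9 passing over all genes and 4 rising over the list alone, as many as had an unadjusted p under 0.05. Their camera adjusted p was 0.0409, or 0.698 with an estimated correlation, 0.107 without knockout library 31 and 0.115 without knockout library 40. Without knockout library 32 it was 4.08e-04, with 2 markers rising over all genes. Without wild-type library 29 it was 0.011, with 1 rising. Trbc2 and Cd3d, with values of 3.16 and 1.87, reached only 0.792 and 1.09 CPM in knockout. Angpt1, H2-Ab1 and H2-Ob reached 0.106, 0.085 and 0.0888 without knockout library 40.

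In the remaining marker lists, Prg2, an eosinophil granule protein, rose from 4.13 ± 1.47 to 41.8 ± 20.8 CPM (log2 fold change 3.34 ± 0.43 SE, edgeR adjusted p = 0.0103) and stayed past the threshold whichever library was left out. It was the only call among 6 basophil, mast cell and eosinophil markers over all genes and over the list alone (camera adjusted p = 0.233, and 0.0332 to 0.374 without knockout library 40 or wild-type library 27). The globin gene Hbb-bs was the only one of 5 erythroid markers to rise, over all genes and over the list alone, from 0.113 to 1.01 CPM (camera adjusted p = 0.213, median 0.11, or -0.0037 with total-count scaling, and 0.0536 to 0.943 without knockout library 31 or wild-type library 25). Haemoglobin counts together came to 0.444 to 3.87 CPM. Vpreb3 was the only one of 7 B cell markers to fall, by 3.02 (camera adjusted p = 0.511), again also over the list alone. The platelet gene Gp9, on chromosome 6, rose by 1.59 among 5 megakaryocyte markers, with 2 rising over the list alone (camera adjusted p = 0.211, and 0.0441 to 0.351 without knockout library 32 or 31). Over all genes, 3 of 7 tested megakaryocyte markers rose without knockout library 32, and 0 without any other single library. The endothelial gene Eng rose by 1.46 among 7 stromal and endothelial markers, with 2 over the list alone (camera adjusted p = 0.358). Among 5 dendritic cell markers 0 passed by edgeR over all genes or over the list alone and 1 had an unadjusted p under 0.05, with Bst2 at -0.40 and Cd209a at -2.37 (camera adjusted p = 0.525). Cd209a was at -2.96 without wild-type library 27, where it passed (edgeR adjusted p = 0.0369), and at -1.12 without wild-type library 25. Without knockout library 40 the adjusted p of Hbb-bs was 0.0773 and of Gp9 0.107, and Vpreb3 and Eng reached 0.066 and 0.0792 without wild-type libraries 25 and 27.

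Across all 30 lists, 11 passed with camera's preset correlation, 7 with higher and 4 with lower members. With an estimated correlation 1 passed, the sex-linked genes (adjusted p = 9.0e-04), and by fry, which asks whether a list's genes move 1 way on balance, 2 passed, the sex-linked and the mature neutrophil genes (fry adjusted p = 0.0311). Of 5 sex-linked genes, 4 rose by edgeR and 1, Xist, fell when adjusted over the list alone. Other divisions of the same 6 libraries into 3 and 3 gave 6 to 14 lists with the preset correlation. The number of lists passing at that correlation was therefore not specific to the labelled division. Those divisions set unequal numbers of each label against each other, so they still hold part of the labelled difference. Apart from the MLL program and MYC targets, which lists passed in them was not compared.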

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

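The fits without wild-type libraries 27 and 29 and without chromosome 6, X or Y genes were chosen after the data were seen. Among named genes, 305 of 498 values with 1 library left out kept direction and side of the threshold. Of the others, 185 lost the call, 6 gained it and 2 reversed. The 498 include values of genes that were not called and so could not lose a call. Of the 65 called named genes, 21 kept the call whichever library was left out. Under the other alternatives the numbers kept, lost, gained and reversed were 782, 92, 24 and 4 of 902. For the lists beyond the MLL program and MYC targets they were 137, 11, 7 and 13 of 168, and 295, 20, 7 and 6 of 328. Where the cause is not plain from fewer genes or libraries, the cause was not tested.

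With 1 library left out, higher genes ranged from 245 (without knockout library 40) to 787 and lower genes from 102 to 440. Lists past the threshold ranged from 8 to 11, the adjusted p of the MLL program from 2.16e-04 to 0.0699 (without knockout library 32), that of MYC targets from 2.84e-08 to 9.04e-06, and the log2 fold change of Rbm5 from 0.24 to 0.42. Reversed directions occurred for Meis1 (-0.103 to 0.0779) and, with adjusted p in these ranges, for mitosis (0.175 to 0.974), p53 targets (0.334 to 0.954), B cells (0.173 to 0.912), DNA replication (0.101 to 0.887) and cholesterol synthesis (0.197 to 0.773).

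Higher and lower genes numbered 1553 and 1054 with DESeq2, where 5 adjusted p-values were undefined, 131 and 71 against a fold of 1.5, and 305 and 148 without wild-type libraries 27 and 29, which leaves 1 wild-type library assumed to vary like the others; with no filter, 836 were lower. With an estimated correlation 1 list passed, with the MLL program and MYC targets both at 0.698, and by fry 2 passed, with these at 0.127 and 0.0741. Without chromosome 6 genes the MLL program was at 0.523, since its Hoxa genes lie there. In the reversals that follow, values in brackets are log2 fold changes for single genes and camera adjusted p-values for lists. Rbm6 reversed with upper-quartile factors (-0.0129) and total counts (-0.093), and mitosis genes with total counts (0.833). With no filter, stem (0.998), B cell (0.576) and dendritic cell (0.894) markers reversed. Without wild-type libraries 27 and 29, Meis1 (0.0432), Ccnb1 (0.137), DNA replication (0.862) and basophil (0.724) genes reversed. In the simulation, with the depth, spread and library number of these data, 1.5-fold changes of better-expressed genes were mostly missed (9.25% recovered). No paired analysis was possible because the groups share no numbers.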

Other observations

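The families in this paragraph were singled out after their values were seen. The stefin and cystatin A genes, a cluster of cysteine protease inhibitors on chromosome 16, rose together in the libraries labelled knockout. All 7 tested members passed the edgeR test, with log2 fold changes from 2.80 to 4.71 and a median of 3.95. Stfa1 went from 147.5 ± 32.3 to 1029 ± 355 CPM and Stfa3 from 4.76 ± 0.501 to 117.8 ± 36.2 CPM (SD over 3 libraries), though reads shared between near-identical members leave single values uncertain. Protocadherin beta genes on chromosome 18, which encode neuronal adhesion molecules, went the other way, with 3 of 5 tested members past the test and a median of -4.26. Pcdhb16 went from 3.85 ± 1.55 to 0.158 ± 0.124 CPM. Collagen VI chains divided, with Col6a6 higher, Col6a3 lower and Col6a4 at 5.34 ± 1.26 and 6.54 ± 2.87 CPM.

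The tests of the next paragraphs were chosen after the results were seen, except the count over divisions of the libraries. Rbm5 stood at a log2 fold change of 0.34 in the libraries labelled knockout. Scaling is argued against, as the lowest value over 4 scalings was 0.22. As to exchanged libraries, 0 correlated best with the other group. The groups also differed fully in sex, so this cannot decide whether single libraries were exchanged by genotype. Nor does it speak of both groups exchanged as a whole. Rbm5 was at 173.6 to 269.0 CPM in every library, so no exchange of labels would give a group without its transcript. A deletion that leaves most of the transcript in place may account for the kept Rbm5 counts. It stays open, because the table holds 1 entry for Rbm5 and no exon can be read alone.

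Chromosome 6 genes were higher in wild-type libraries 27 and 29 than in the other 4, by a median of 0.36 on the log2 scale (bootstrap 95% interval 0.34 to 0.39), and 87.2% of the 390 genes with a mean log2 CPM above 4 had that direction. The bootstrap resampled genes, which are not independent replicates, so its interval holds no spread between libraries. Scaling is argued against, as no other chromosome moved by more than 0.0419. An extra copy of the whole chromosome in many cells of these libraries is a candidate explanation, with every one of 8 windows of 20 Mb above 0 and the lowest at 0.286. A lower copy number in the knockout libraries as the whole cause of the low Hoxa genes is argued against, since the highest Hoxa value was -1.09, a larger fall than the 0.585 on the log2 scale between 3 copies and 2. Over the 390 genes, wild-type library 25 minus the knockout mean had a median of -0.00411, so the rise did not divide the libraries by label. No biological explanation that follows the knockout label was tested for the low Hoxa genes.

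Mature neutrophil genes were higher in the libraries labelled knockout. A single added neutrophil population in different amounts would keep the genes' increments in 1 ratio between libraries, with an SD of their log2 ratio below 0.5. Increments were taken over the wild-type mean, as if the other cells of each knockout library stood at that level. Over the 20 genes that SD was 1.40 for knockout libraries 31 and 32 (bootstrap 95% interval 0.75 to 2.00). It was 1.10 for 31 and 40 (0.586 to 1.56) and 0.529 for 32 and 40 (0.33 to 0.675), where 0.5 was chosen after the results were seen. The bootstrap resampled genes, which are not independent replicates, so these intervals hold no spread between libraries. The 2 pairs whose intervals lie above 0.5 share library 31, so they bear on 1 makeup in all 3 libraries only through that library. A single gene, Chil3, widens both SDs. Its ratio of increments was 0.0627 for 31 to 32 and 0.0589 for 31 to 40, with Camp next lowest at 0.554 and 0.315. Without a spread between libraries the intervals cannot decide whether the makeup differed, and an added population stays open. Sex of the cells cannot be told apart from the label, because 0 groups held libraries both with and without Y-linked transcripts, and the knockout itself and more mature leukemia cells may also account for it.

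The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The labelled division gave 1368 calls and the highest of the others 0, so 1 division reached that count. For lists past the threshold the values were 11 and 14, and 7 divisions had as many. The MLL program's smallest adjusted p elsewhere was 9.88e-04 against 0.00712 (2 divisions as small), and that of MYC targets 4.77e-06 against 1.38e-07 (1 division).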
